A study of Mus musculus with 6 samples.

How the data were processed

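Lung MSC were isolated by dissociation and flow cytometry for the reporter colours mT and mG, RNA was extracted, and unstranded libraries were made by a sequencing provider, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, cutadapt 5.0, Trimmomatic 0.38, STAR and edgeR 4.0; the genome build, the annotation and the counting tool are not given in the sources used here. Because the build is not given, only the chromosome in the table is printed. Without strand, reads from a gene and an overlapping antisense gene cannot be told apart, which concerns any gene named here that has such a partner.

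The authors deposited 1 table with a row per gene and, per the file headers, whole-number counts for each of the 6 libraries. Every one of the 20645 rows has a count in at least 2 libraries, so genes below that are not listed. The RPKM columns are, per the file headers, the authors' length- and depth-scaled values, and equalled the counts divided by the listed gene length (in bases, by the authors) and 1 constant per library. The columns named TMM, per the file headers, hold a signal that equals the counts scaled to a total common to the libraries. The authors' log2 fold changes and log2 mean levels, their likelihood-ratio score, their p-value with its adjustment, and −log10 of that p-value come from the deposited table, whose name mentions upper-quartile normalization and removal of unwanted variation. The RPKM and TMM columns were used only to check the counts, and the authors' comparison only where the text names it.

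Columns were assigned to samples by the library names in the labels. Total counts were 19429138, 16853561 and 16947324 in mT replicates 1 to 3 and 19185862, 18871952 and 18349874 in mG. At these depths 3 counts correspond to 0.154 to 0.178 CPM, the floor for a gene without counts in a library; for a gene without counts in a group, the floor is 3 counts over the 3 libraries together. Intervals and floors cover counting error only. Rows without a gene name hold 0.013% to 0.035% of counts per library. Where a symbol has several rows, the row with more counts carries it. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.903 to 0.976 within groups and 0.881 to 0.934 between them, and no pair of libraries was identical.

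Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), with TMM factors of 0.926 to 1.134, filterByExpr on the group with a minimum count of 10, and Benjamini-Hochberg adjustment over 13566 genes at 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts over TMM-scaled library totals. Gene lists were tested with camera and fry of limma 3.58.1 on log2 CPM with a prior count of 2; 34 lists were fixed before the data were examined, as were the groups, the tests and a first set of alternatives. Lists with fewer than 3 tested members were not tested as lists. Counts within a list are also given adjusted over the list alone.

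Genes named in the text follow a rule fixed before the data were examined. It takes 13 genes in every case (Tbx4, Tbx5, Tbx2, Foxf1, Tcf21, Pdgfra, Pdgfrb, Ly6a, Thy1, Eng, Ptprc, Pecam1 and Epcam) and any reporter row, of which the table has 0. It adds the 8 called genes with the largest log2 fold change in each direction at a mean log2 CPM of at least 3 without overlap between groups, leaving out predicted gene models, and up to 3 members with the smallest adjusted p of each list described. The panel for Hoxa5 and the labels for Slit3 and Igfbp2 in the plots were chosen after their values were seen.

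Replicate numbers 1 to 3 occur in both groups. Correlations of the deviations from group means between mT and mG libraries of the same number were 0.24, 0.18 and 0.3, each above 0.1, and their mean of 0.24 compares with 0.02 for the highest of the other 5 pairings. By the rule fixed for this check the numbers are treated as pairing the samples, though the highest of 6 pairings is weak evidence. The pairing comes from the data, since the labels do not say what a number stands for. The main test, fixed before the data were examined, has no block. A value with the replicate number as a block is therefore printed beside a result whose call it changes.

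Alternatives planned before the data were examined were RLE and upper-quartile normalization, no expression filter, a filter of CPM at least 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block, 1 factor of unwanted variation from residuals on upper-quartile normalized counts (own implementation), each library left out, and for lists an estimated correlation and fry. DESeq2 was run with its default filter, and adjusted p-values it leaves empty stay empty. Alternatives for normalized values (pseudocounts and a filter on values) did not apply, since counts are held. A likelihood-ratio test, both replicate 2 libraries left out, blocked fits without 1 replicate number and blocked fry were added after seeing the data.

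The tests were checked on simulated data with the real means, dispersions and library sizes, in which 200 of 13566 genes were changed between mT and mG. The quasi-likelihood test recovered 8% of 50 genes changed by 1 on the log2 scale, 76% at 2, 100% at 4 and 100% at 6, all with the right sign, and 5.96% of its calls were false. Of calls by the likelihood-ratio test 27.7% were false, and of those by DESeq2 32.5%, at the adjusted p of 0.05 used throughout. With the replicate block 8.16% were false, and with 1 factor of unwanted variation 9.15%. The genes of this single simulated set were drawn independently, and DESeq2 was given the 13566 filtered genes, where its real fit had 20645. No pair effect and no unwanted factor was simulated, so the checks of the block and of that factor cover data without them. These shares depend on such settings and need not hold in the real data.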

Results

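Gene expression was measured by RNA sequencing in 6 libraries of mesenchymal stromal cells (MSC) from the lungs of C57BL/6 mice. The mice carried a doxycycline-dependent Cre driven by the lung mesenchyme regulator Tbx4, and a membrane reporter that switches from red (TdTomato) to green (GFP) fluorescence on Cre recombination. Doxycycline was given from embryonic day 6.5 to postnatal day 1, so green cells are those in which the driver was active, or which descend from such cells. Lung tissue was dissociated with enzymes and cells were sorted by flow cytometry into a red group (mT, 3 libraries) and a green group (mG, 3 libraries). The comparison asks how these 2 subpopulations of resident lung MSC differ in gene expression. Total counts per library ran from 16853561 to 19429138 over 20645 listed genes. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. Values are CPM, that is counts scaled to the library total, as mean ± SD with n = 3 per group, and fold changes are mG over mT.

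Cells of the mT group carried transcripts of the developmental transcription factors Pou3f4, Alx4, Sp9 and Meox2 that were nearly absent from mG, while mG cells had more of the chemokine Cxcl12, the complement inhibitor C4bp and the NKG2D ligand Ulbp1. With the replicate number as a block Cxcl12 and C4bp did not pass, at adjusted p = 0.0522 and 0.0664. In edgeR's quasi-likelihood test on 13566 genes, 123 passed a Benjamini-Hochberg adjusted p of 0.05, of which 27 were higher and 96 lower in mG. At least a 2-fold change was seen in 119 of them, 24 higher and 95 lower, and 80 of the lower genes fell by over 4-fold. All 123 had values that did not overlap between the groups, as did 20.8% of all genes tested, where chance gives 10%. The count moved with every library left out: it was 28, 25 and 20 without mT replicates 1, 2 and 3, and 71, 362 and 32 without mG replicates 1, 2 and 3. Called under all 6 of these omissions were 17 genes, all of them lower in mG. With the block 108 genes passed, 63 of them among the 123.

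**Figure D1:**
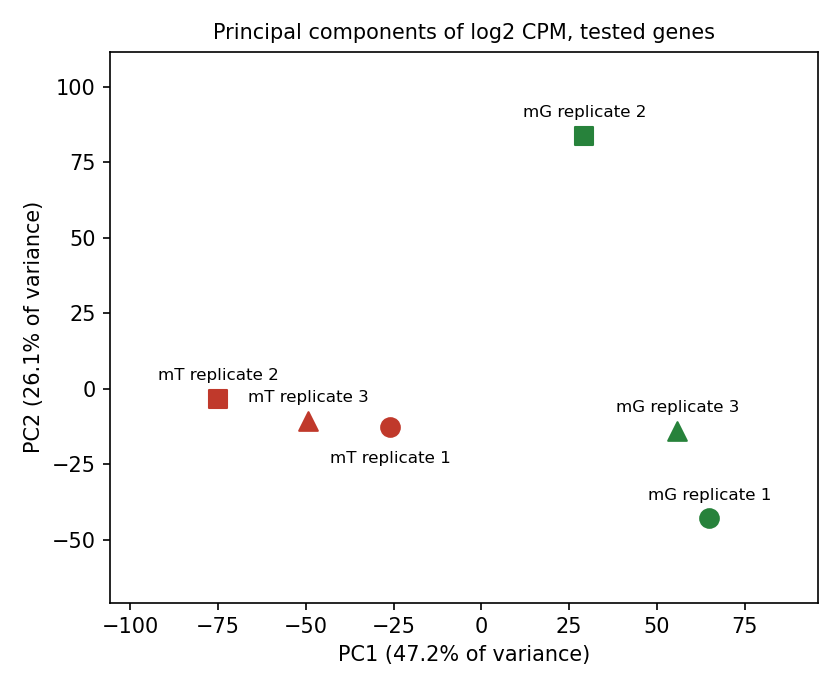
Principal components of log2 CPM over the tested genes, PC1 (47.2% of variance) on the x axis and PC2 (26.1%) on the y axis, 1 point per library, red for mT and green for mG. The groups part along PC1, mT between -74.9 and -25.9 and mG between 29.3 and 65, and mG replicate 2 stands apart at 83.8 on PC2.

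**Figure D2:**
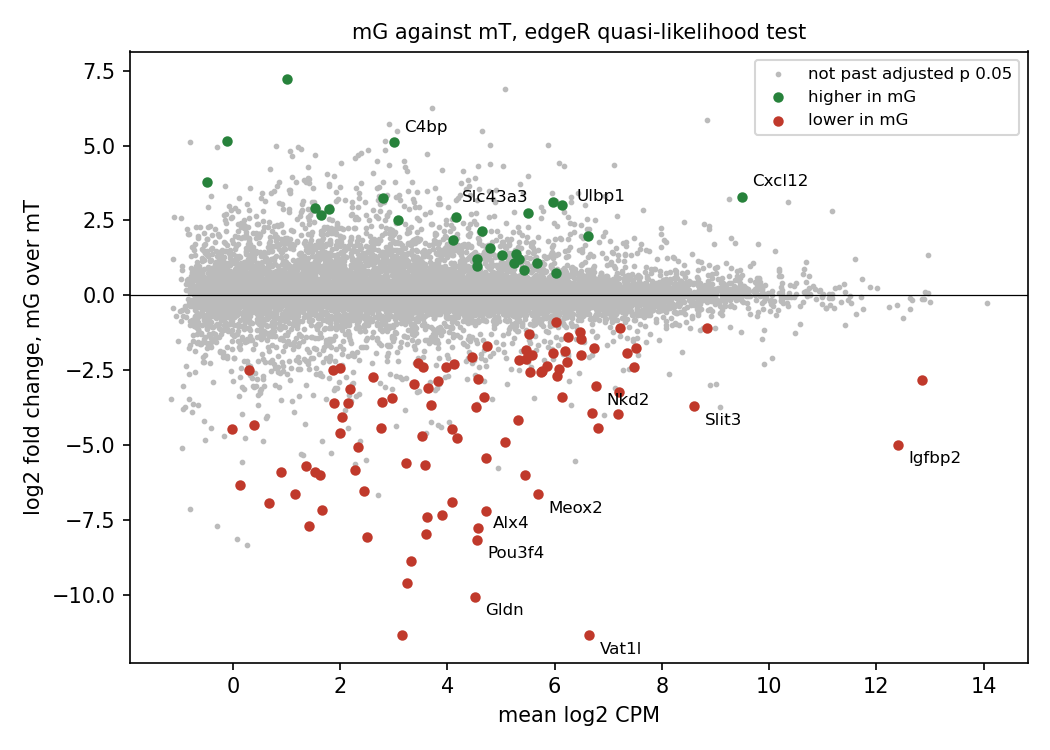
Log2 fold change of mG over mT (y axis) against mean log2 CPM (x axis), 1 point per gene tested, with the 27 genes higher in mG in green and the 96 lower in mG in red. Most called genes lie below 0, and Vat1l and Gldn are among the lowest.

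Among called genes with a mean log2 CPM of at least 3, those with the largest decrease in mG were close to background there. Vat1l on chromosome 8 had 201 ± 77.9 CPM in mT and 0.0727 ± 0.126 CPM in mG, from a total of 4 counts, with adjusted p = 0.00686. Pou3f4 on chromosome X, which encodes a POU-domain transcription factor of inner ear mesenchyme, fell from 46.5 ± 8 to 0.15 ± 0.117 CPM, a log2 fold change of -8.15 ± 0.44 (SE) and adjusted p = 0.00626. Alx4 on chromosome 2, a homeobox gene of craniofacial and limb mesenchyme, fell from 47.5 ± 22.6 to 0.207 ± 0.0644 CPM with adjusted p = 0.00842. Snap91, which encodes a clathrin coat assembly protein, fell from 24.1 ± 11.1 to 0.0898 ± 0.0642 CPM with adjusted p = 0.00882. Gldn, which encodes gliomedin, had 2 counts in mG, a ratio of mT to mG of 1280 with a 95% counting interval of 353 to 10500 and adjusted p = 0.00626. The transcription factor gene Sp9 also had 2 counts in mG, a ratio of 552 with an interval of 152 to 4560 and adjusted p = 0.0131. Kank4 had 1 count in mG, a ratio of 1030 with an interval of 184 to 40600 and adjusted p = 0.0396, and its mT values spread widely at 18.9 ± 19.8 CPM. Prkcq, which encodes protein kinase C theta, had no count in mG and was at least 322-fold lower there, taken against a floor of 3 counts over the group, with adjusted p = 0.0428, or 0.0521 with the replicate number as a block.

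Among called genes with a mean log2 CPM of at least 3, those with the largest increase in mG had smaller folds. Called genes below that level were not ranked, and the largest rise among them was 7.21 on the log2 scale. Cxcl12 on chromosome 6, which encodes the ligand of the chemokine receptor Cxcr4, rose from 133 ± 56.4 to 1310 ± 474 CPM, 9.83-fold, with adjusted p = 0.0369, or 0.0522 with the block. C4bp on chromosome 1, which encodes an inhibitor of complement, rose 34.4-fold from 0.436 ± 0.337 to 15.4 ± 3.84 CPM with adjusted p = 0.0366, or 0.0664 with the block. Ulbp1 on chromosome 10, which encodes a ligand of the NK cell receptor NKG2D, rose from 15.3 ± 1.93 to 124 ± 49.1 CPM with adjusted p = 0.018. Slc43a3, a solute carrier gene, rose 8.62-fold with adjusted p = 0.037. Tmem176b rose 6.72-fold, Stxbp2, which acts in vesicle exocytosis, 6.06-fold, the oxysterol hydroxylase gene Cyp39a1 5.65-fold and the ninein-like gene Ninl 4.45-fold. Their adjusted p-values were 0.0448, 0.0369, 0.0244 and 0.03, and with the block 0.0593, 0.0794, 0.0593 and 0.0672.

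**Figure D3:**
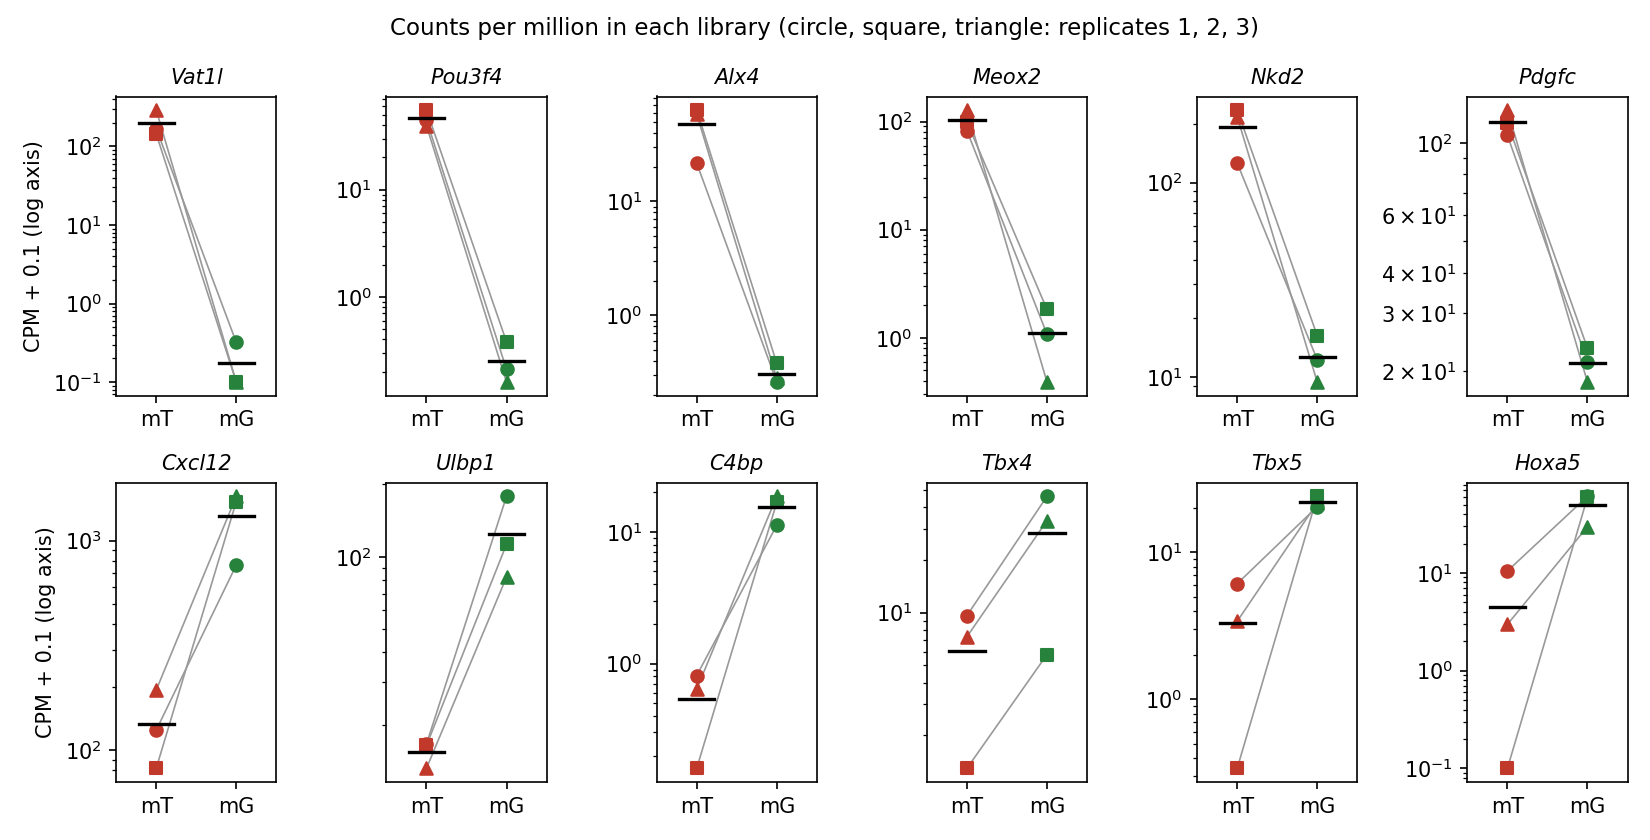
CPM plus 0.1 on a log axis (y) in each mT (red) and mG (green) library for 12 genes, with grey lines joining libraries of the same replicate number and black bars at group means. Vat1l, Pou3f4, Alx4, Meox2, Nkd2 and Pdgfc lie lower in all 3 mG libraries, and Tbx4, Tbx5 and Hoxa5 vary widely within mT, with replicate 2 lowest.

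Tbx4 itself, the gene whose regulatory sequence drives the Cre system, had 5.97 ± 4.29 CPM in mT and 28.2 ± 20.5 CPM in mG. Its log2 fold change was 2.23 ± 0.93 with adjusted p = 0.343, and 2.24 with adjusted p = 0.028 when replicate numbers were a block, since mG exceeded mT by 4.8, 4.73 and 4.62 times within pairs 1 to 3. Among 20 tested lung mesenchyme transcription factors, 2 passed the test, both lower in mG, and adjusted over the list alone 3 were higher and 2 lower. Those that passed were Meox2, a homeobox gene of mesoderm, which fell from 103 ± 22.9 to 1 ± 0.72 CPM (adjusted p = 0.00965), and Twist1, a basic helix-loop-helix regulator of mesenchyme, which fell from 110 ± 12.4 to 42.1 ± 7.05 CPM (adjusted p = 0.0281). The lung mesenchyme genes Tbx5 (3.19 ± 2.9 CPM in mT, 22 ± 1.83 in mG) and Foxf1 (11.1 ± 7.93 and 49.7 ± 2.21) did not pass, with adjusted p = 0.224 and 0.137. Tcf21 (0.533 ± 0.463 and 12.1 ± 7.94 CPM), Gata6 (5.18 ± 2.49 and 22.1 ± 6.81) and Tbx2 (12.1 ± 7.33 and 33.3 ± 21.7) did not pass either, with adjusted p = 0.147, 0.117 and 0.379. All 5 were higher in mG within each pair. In mT replicate 2 the counts of Tbx4, Tbx5, Foxf1 and Tcf21 were 20, 4, 70 and 0, against 188, 119, 390 and 15 in mT replicate 1.

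Of 32 gene lists with at least 3 tested members, 3 passed camera at a preset correlation of 0.01: Hox genes and proliferation genes, higher in mG, and Wnt pathway genes, lower in mG. None of the 3 passed when the correlation between genes was estimated, nor in the directional form of the self-contained test fry. In fry's mixed form, which takes changes in either direction, adjusted p was 0.00174 for Wnt, 0.0401 for Hox and 0.292 for proliferation genes. Further lists also passed that form, among them pericyte, FGF and retinoid genes at a lower adjusted p of 0.000844. The mixed form therefore does not single out Wnt or Hox genes. At the preset correlation each of the other 9 splits of the 6 libraries into 3 and 3 gave at least 4 lists. The Hox and proliferation lists were each called in 7 of the 10 splits, the Wnt list in the real one alone. Hox genes, which mark position along the body axis, had a median log2 fold change of 3.19 over 19 tested members with adjusted p = 2.31e-08, and adjusted p = 0.884 with an estimated correlation. Fitted values were above 0 for 18 of them, no member passed over all genes, and adjusted over the list alone 13 were higher and 1 lower. Hoxa4 had 0.235 ± 0.21 CPM in mT and 3.81 ± 1.19 in mG (adjusted p = 0.114) and Hoxa2 had 0.409 ± 0.254 and 4.96 ± 2.85 CPM (adjusted p = 0.0891), while Hoxc13 had 7.81 ± 1.92 and 0.528 ± 0.692 CPM (adjusted p = 0.18). The 18 genes fitted above 0 summed to 1092, 38 and 404 counts in mT replicates 1 to 3, and to 4182, 5195 and 3757 counts in mG.

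All 25 proliferation genes were fitted above 0, with a median of 1.34 and adjusted p = 4.42e-07, but adjusted p = 0.884 with an estimated correlation, and none passed singly, over all genes or adjusted over the list alone. Ccne1 (13.2 ± 0.617 CPM in mT, 22.4 ± 8.98 in mG), Mcm3 (17.2 ± 6.9 and 41.8 ± 24.2) and Bub1b (10.8 ± 4.3 and 27.3 ± 17.7) had adjusted p from 0.308 to 0.319. All 3 were higher in mG within each pair of replicate numbers. Mean log2 CPM of the list was 6.32, 5.03 and 4.44 in mG replicates 1 to 3 and 4.63, 4.35 and 3.23 in mT, likewise higher in mG within each pair. Among 26 Wnt pathway genes the median was -0.70 with adjusted p = 0.00461, or adjusted p = 0.545 with an estimated correlation, and 19 were fitted below 0. The only member to pass was Nkd2, which encodes an inhibitor of Wnt signalling and fell from 193 ± 59.1 to 12.6 ± 3.47 CPM (adjusted p = 0.00965). Adjusted over the list alone 2 were lower. Lef1 (2.23 ± 0.7 and 0.315 ± 0.216 CPM) and the Wnt antagonist gene Dkk2 (40.2 ± 21 and 11.3 ± 3.69 CPM) had adjusted p = 0.112 and 0.167.

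**Figure D4:**
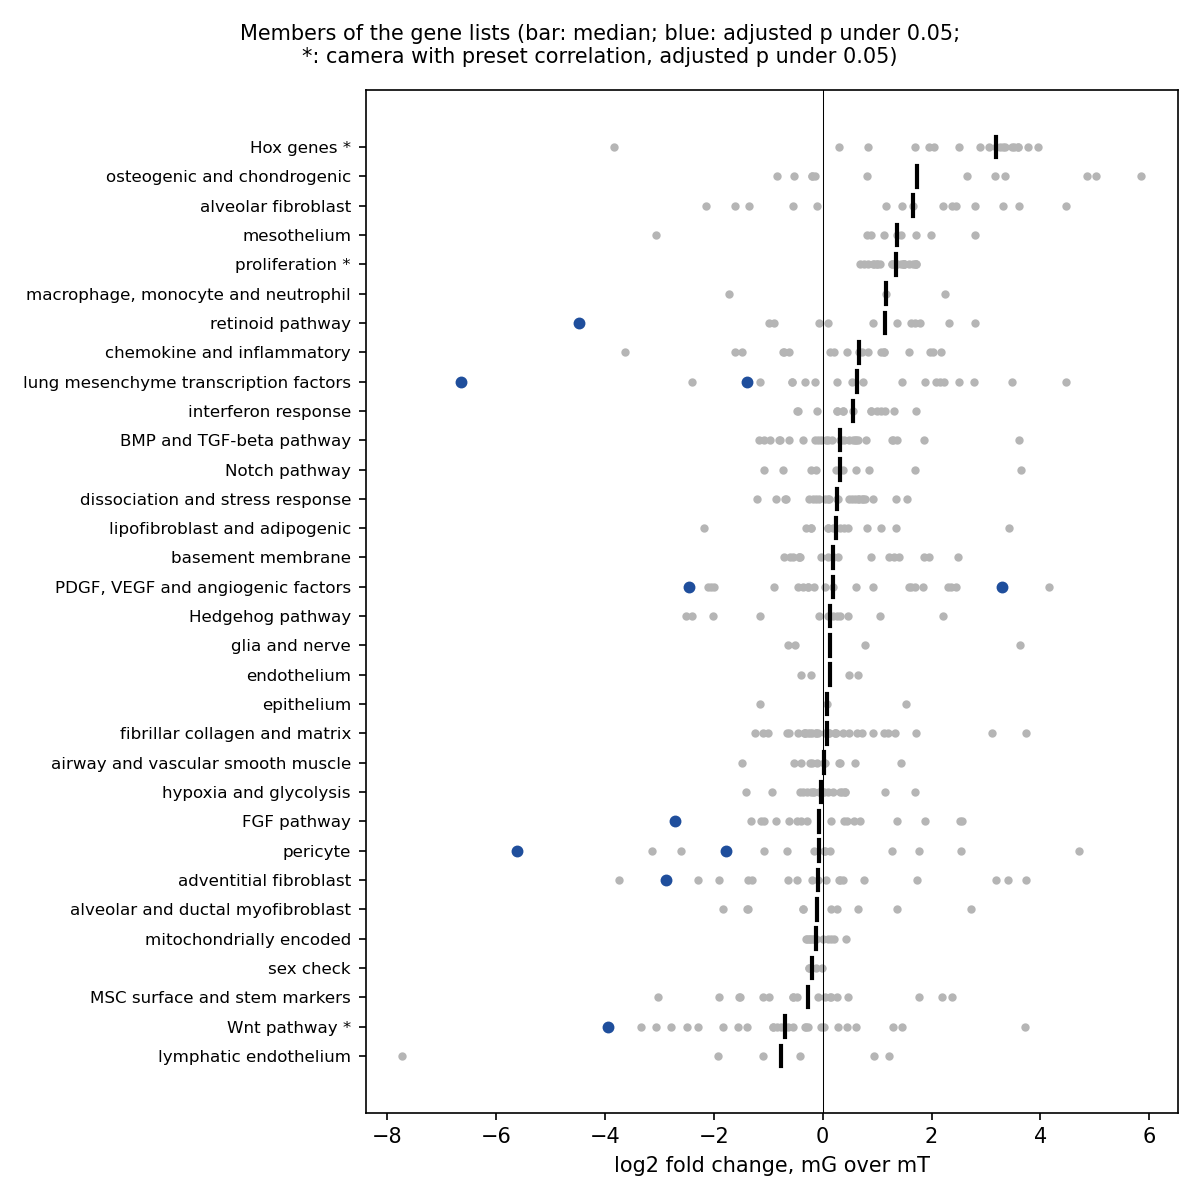
Log2 fold change of mG over mT (x axis) for each tested member of 32 gene lists (y axis), with black bars at list medians, blue points for members past an adjusted p of 0.05 and an asterisk for the 3 lists past camera at the preset correlation. Hox genes have a median of 3.19 and Wnt pathway genes of -0.70.

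Few members of the growth factor and signalling lists passed. Of 23 tested PDGF, VEGF and angiogenic factors, Cxcl12 rose and Pdgfc, which encodes a ligand of PDGF receptor alpha, fell from 115 ± 10.3 to 21 ± 2.5 CPM with adjusted p = 0.00626. Adjusted over the list alone, 6 were higher and 3 lower. Vegfd, at 105 ± 45.1 CPM in mT and 573 ± 266 in mG, had adjusted p = 0.104. In the FGF pathway list 1 of 18 passed, Flrt3, which fell from 10.4 ± 1.06 to 1.57 ± 0.794 CPM with adjusted p = 0.05 after rounding, or 0.0664 with the block. Of 12 retinoid genes, Crabp1, a retinoic acid binding protein gene, fell from 1.71 ± 0.748 to 0.0716 ± 0.033 CPM with adjusted p = 0.0399, or 0.0659 with the block. Aldh1a1 (237 ± 70.7 and 774 ± 317 CPM) and Rdh10 (22 ± 1.84 and 11.7 ± 1.66 CPM), both of retinoic acid synthesis, had adjusted p = 0.124 and 0.092. No Hedgehog gene passed, but the coreceptor gene Gas1 (78.1 ± 34.3 and 13.5 ± 9.15 CPM) went from adjusted p = 0.152 to 0.0366 with the block. No gene of the BMP and TGF-beta list passed, and Bmp3 (0.981 ± 0.648 and 12.1 ± 11.1 CPM) went from 0.166 to 0.0477 with the block. Adjusted over the list alone, 1 FGF gene was lower, 1 Hedgehog and 1 retinoid gene were higher and 2 of each lower, and 0 of the BMP and TGF-beta genes passed.

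Few markers of mesenchymal cell types passed, all of them lower in mG. Of 14 pericyte genes 2 passed, Ebf1, which fell from 165 ± 29.5 to 48.4 ± 8.56 CPM (adjusted p = 0.0234), and the cation channel gene Trpc6, which fell from 18.2 ± 8.56 to 0.362 ± 0.22 CPM (adjusted p = 0.0243, or 0.0599 with the block). Of 19 adventitial fibroblast genes 1 passed, Pcolce2, which fell from 24.7 ± 10.4 to 3.37 ± 1.15 CPM (adjusted p = 0.0399). Col14a1 of the same list had 14.9 ± 15.7 CPM in mT and 158 ± 49 in mG with adjusted p = 0.2. None of 15 alveolar fibroblast genes, 13 smooth muscle genes or 33 fibrillar collagen and matrix genes passed. Adjusted over the list alone, 4 pericyte and 2 adventitial fibroblast genes were lower, 4 alveolar fibroblast genes were higher and 1 lower, and 0 smooth muscle or matrix genes passed. Mylk, which encodes myosin light chain kinase, had 100 ± 77.8 CPM in mT and 269 ± 199 in mG, with adjusted p = 0.474, or 0.0465 with the block.

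None of 18 tested MSC surface and stem markers passed over all genes, while adjusted over the list alone 3 were higher and 1 lower. Vcam1 (34.5 ± 19.6 CPM in mT, 159 ± 25.8 in mG), Abcg2 (19.8 ± 8.39 and 67.7 ± 14.8) and Cd9 (263 ± 82.1 and 91.5 ± 24.3) had adjusted p = 0.077, 0.0829 and 0.0819, and that of Cd9 was 0.0384 with the block. Pdgfrb had 658 ± 68 CPM in mT and 675 ± 117 in mG with adjusted p = 0.97. Pdgfra (262 ± 52.2 and 180 ± 60.6 CPM), Eng (289 ± 22 and 199 ± 68.7), Thy1 (506 ± 216 and 236 ± 88.3) and Ly6a, which encodes Sca-1 (520 ± 36.9 and 140 ± 114), had adjusted p from 0.294 to 0.439.

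Markers of other cell types varied in level. Ptprc, the pan-leukocyte gene, had 0 to 6 counts per library, none of 4 lymphocyte genes in the table was tested, and the epithelial gene Epcam had no row. None of 3 tested macrophage, monocyte and neutrophil genes passed, while adjusted over the list alone 2 were higher and 1 lower. An adjustment over 3 genes is mild, and 1978 of 13566 genes had an unadjusted p under 0.05 in the quasi-likelihood test. Csf1r had 1.62 ± 0.638 CPM in mT and 7.72 ± 1.43 in mG (adjusted p = 0.0728). Lyz2 had 13.2 ± 3.59 and 3.99 ± 2.35 CPM (adjusted p = 0.235). The endothelial gene Pecam1 had 139, 0 and 28 counts in mT replicates 1 to 3 and 0, 3 and 0 in mG, a ratio of mT to mG of 59.4 with a 95% counting interval of 20 to 291, and was not tested, since too few libraries reached the minimum count, while Flt1, also of the endothelial list, had 109 ± 60 CPM in mT and 172 ± 130 in mG with adjusted p = 0.818. Of the osteogenic and chondrogenic genes none of 12 passed, 2 were higher adjusted over the list alone, and mG replicate 2 stood apart in them with a mean log2 CPM of 6.07, against 1.9 and 2.47 in mG replicates 1 and 3. Sox9, a regulator of cartilage, had 3097 counts in mG replicate 2 and 149 and 139 in mG replicates 1 and 3. Of the 32 lists, 29 did not pass camera, with adjusted p from 0.194 to 0.962. In the airway and vascular smooth muscle, endothelium, epithelium, glia and nerve, Hedgehog and retinoid lists the median was above 0 and the test's direction downward.

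The authors' deposited table of the same comparison lists 1248 genes past an adjusted p of 0.05, 658 higher and 590 lower in mG. Of these, 796 were among the 13566 genes tested here. The authors' p-values stand beside a likelihood-ratio score, whereas the calls here come from a quasi-likelihood test. Log2 fold changes of both had a Pearson correlation of 1, after rounding, across the tested genes. The authors' calls include 118 of the 123 genes called here. In the authors' deposited table Tbx5, Foxf1 and Tcf21 have adjusted p of 0.0106, 0.00436 and 6.28e-05, and Tbx4 has 0.0752. Of the genes called in the authors' deposited table, 254 have overlapping groups, and in 136 a single library holds over 75% of the summed CPM, which is mG replicate 2 for 80 of them.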

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

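Tests added after seeing the data are the likelihood-ratio test, the omission of both replicate 2 libraries, blocked fits without 1 replicate number and blocked fry. The count of 123 genes (27 higher and 96 lower in mG, 119 with at least a 2-fold change) stayed within 1.5 times under RLE and upper-quartile normalization and both other filters. With limma-voom it was 92, within that bound, but the 17 of these higher in mG were below it. With 1 factor of unwanted variation it was 483 (147 higher, 336 lower, 385 at 2-fold), with DESeq2 960 (476, 484, 824) and with the likelihood-ratio test 766 (360, 406, 701), and all 123 genes were among each of these. In simulated data each of these made more false calls than the quasi-likelihood test, at shares that need not hold in the real data. Those data held no unwanted factor, so they cannot show whether the calls gained with such a factor are false. With the replicate block the count was 108 (35 higher, 73 lower), of which 63 were among the 123. The block ended 10 and added 5 calls among 117 named genes tested, each given in the report, and changed no other call of a named gene or list. Without 1 library it ran from 20 to 362, with 0 to 132 higher, 20 to 230 lower and 20 to 333 at 2-fold, the highest without mG replicate 2 and the lowest without mT replicate 3. Without mT replicate 3 no gene was higher by edgeR's quasi-likelihood test, where 626 had an unadjusted p under 0.05 in that direction. Without both replicate 2 libraries it was 46 (10 higher, 36 lower, 46 at 2-fold), 24 of them among the 123. Blocked fits gave 0 genes without replicate 1 and 0 without replicate 3, where the unadjusted p was under 0.05 for 1716 and 1214 genes, and 797 (418 higher, 379 lower, 752 at 2-fold) without replicate 2; these fits hold 2 pairs, which leaves 1 residual degree of freedom, and no other tool was run there. The cause was not tested for any of these moves. Of the 25 named genes called, 8 were called in every fit with 1 library left out, and no named gene called in either of the fits compared changed sign under any alternative. The adjusted p of Tbx4 ran from 0.00997 to 0.659 over its alternatives, that of Cxcl12 from 2.04e-12 to 0.261, and that of Pou3f4 from 5.1e-59 to 0.152.

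The 3 gene lists past camera became 0 with an estimated correlation, 0 with directional fry and 0 with blocked directional fry. In fry's mixed form the Wnt and Hox lists passed, as did further lists, some at a lower adjusted p. By camera the lists past the threshold were 3 to 5 without 1 library, 5 being without mG replicate 1. Lists not called with all libraries gained a call in the same direction: interferon response without an expression filter (adjusted p = 0.015), without mT replicate 3 (0.0379), without mG replicate 1 (9.72e-05) and in the blocked fit without replicate 1 (1.24e-05), smooth muscle without mG replicate 1 (0.0319), endothelium without mT replicate 2 (0.00807) and alveolar fibroblast in the blocked fit without replicate 3 (0.00467). The hypoxia and glycolysis list, not called with all libraries, had the opposite direction, higher in mG, with adjusted p = 0.0248 without both replicate 2 libraries and 0.0256 in the blocked fit without replicate 2; the cause was not tested. The filter left 7079 listed genes untested, some for low counts and some because too few libraries reached the minimum, such as Emcn and Pecam1. Depth limits genes with few counts: a gene with no count in a library is below 0.154 to 0.178 CPM there.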

Other observations

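Genes in this part outside the naming rule were chosen after their values were seen and stand for no class of genes. Pax3 fell from 85.3 ± 25.4 to 1.32 ± 0.685 CPM (mean ± SD, n = 3 per group; edgeR adjusted p = 0.00882), and the T-box gene Tbx15 from 275 ± 52.6 to 17.7 ± 10.4 CPM (adjusted p = 0.0314). Trps1, a zinc finger gene of cartilage and hair, fell from 97.1 ± 12.8 to 19 ± 4.96 CPM (adjusted p = 0.0154). The guidance ligand gene Slit3 fell from 726 ± 77.2 to 55.8 ± 11.7 CPM (adjusted p = 0.00626) and its receptor gene Robo2 from 32.2 ± 14.7 to 1.47 ± 1.03 CPM (adjusted p = 0.0434). Among abundant genes, Igfbp2 fell from 10600 ± 4630 to 333 ± 116 CPM (adjusted p = 0.0232, or 0.0521 with the replicate block). The collagen gene Col12a1 fell from 13000 ± 2290 to 1810 ± 274 CPM (adjusted p = 0.0281, or 0.0804 with the block). The Wnt coreceptor gene Lrp5 fell from 144 ± 21.5 to 36.4 ± 3.4 CPM (adjusted p = 0.00882).

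Higher in mG were the corepressor gene Tle1, at 18.2 ± 1.36 CPM in mT and 46.5 ± 2.31 in mG (adjusted p = 0.0131), and the Hox cofactor gene Meis1, at 14.2 ± 2.78 and 32.7 ± 2.08 CPM (adjusted p = 0.048, or 0.0741 with the block). Fendrr, a long noncoding RNA gene next to Foxf1, rose from 1.29 ± 0.714 to 12.5 ± 1.56 CPM (adjusted p = 0.04, or 0.0696 with the block). Leaving out a library ended the call of every gene higher in mG at least once, while Pax3 and Slit3 were called in all 6 such fits.

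Tests of depth, of scaling and of a list's own correlation as a fixed value were chosen only after the result was seen; the other tests below were set down before. The first pattern is the unevenness within mT of the 18 Hox genes fitted above 0, with 1092, 38 and 404 counts in replicates 1 to 3. The 1 tested Hox gene fitted below 0, Hoxc13, lacks it, with 116, 131 and 162 counts. For the 18 genes a lower depth of mT replicate 2 is argued against. That library had 5.72% of their counts expected from its depth and the other mT libraries. Its total of 16853561 counts was near the 16947324 of mT replicate 3. A candidate explanation is that mT libraries hold a varying share of cells with the mG profile. The 18 Hox genes stood at a median of 20.9% of their mG mean in mT replicate 1 (quartiles 18.7% and 48.3%) and 11.5% in replicate 3. Another 110 genes outside the lists, also high in mG and nearly absent from mT replicate 2, stood at 16.5% and 8.87%. Such a share of cells would dilute genes read almost only in mT. Over 47 of these the median log2 ratio to mT replicate 2 was -0.8 in replicate 1 (95% bootstrap interval -1.09 to -0.15, where -0.34 was needed). In replicate 3 it was -0.44 (-0.67 to -0.08, where -0.18 was needed). Both medians lie further below 0 than needed. The intervals resample genes, which may vary together, and measure no spread between samples. A further 29 abundant genes of the mG profile were picked as nearly absent from mT replicate 2. Hoxa5 and Hoxb4 are among them, so the set is not independent of the pattern. Of the 29 genes 0% stood in mT replicate 1 below 5% of their lowest mG library. Their median there was 20.8% of the mG mean and 42.4% of the lowest mG library. The 5% bound lies below the share of 20.9%, and Smoc1 met it with 7.75 CPM, against 95.7 in its lowest mG library. Such a share is not all that differs among the mT libraries: 7 of the 29 genes, Eln among them, stood in mT replicate 1 above their lowest mG library, and endothelial genes nearly absent from mG had the same order, with 662, 0 and 105 counts of Emcn in mT replicates 1 to 3 against 7, 0 and 1 in mG, 134, 0 and 11 of Cdh5 against 0 in mG, and 139, 0 and 28 of Pecam1. Some genes higher in mG stood below the share of 20.9% in mT replicate 1. Mannr had 1, 0 and 0 counts in mT replicates 1 to 3, against 65, 81 and 67 in mG. Bdkrb1 had 1, 0 and 1 counts in mT, against 27, 47 and 18 in mG. Fendrr was nearer to that share, with 40, 10 and 21 counts in mT against 196, 290 and 223 in mG. The called genes were not tested as a set against it. Cells of other kinds in mT replicates 1 and 3 were not tested as the origin of the Hox transcripts. Unequal recombination of the reporter, an unequal sort, and a true difference between the subpopulations of separate samples remain open, and the design has no test of them.

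The second pattern is mG replicate 2, with 58011 counts of Col2a1, 15863 of Comp and 3097 of Sox9, where mG replicates 1 and 3 had 13 and 147, 6 and 23, and 149 and 139. The scaling of that library is argued against by counts before any scaling. In these the cartilage genes described below had a median log2 ratio to the other mG libraries of 2.85 (95% bootstrap interval over genes 1.98 to 4.4). A mislabelled mT library is argued against by 71 genes read almost only in mT. They stood in mG replicate 2 at a median of 4.5% of their mT level. Cells of a cartilage type may be present: of 30 further cartilage genes, none of them in another list and 1 of which (Trps1) had been seen, 24 were in the table and 75% of these were highest in mG replicate 2, against 24.8% of all tested genes, with a median log2 ratio of 2.57. That share lies between the bounds set down for and against, and 12 of the 24 had at least 1 CPM in both other mG libraries, so cartilage cells and MSC expressing cartilage genes cannot be told apart; the sort on reporter colour alone would not remove such cells. No biological explanation other than cells of a cartilage type was tested.

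The third pattern is the proliferation list, higher in mG at the preset correlation with no member called. Members that vary together may be read as independent genes, since their estimated correlation was 0.912 and camera with that as a fixed value gave p = 0.195, and the list was called in 7 of the 10 splits of the 6 libraries into 3 and 3. Whether mG replicate 1, the library with the highest mean of the list, carries it alone stays open: adjusted p was 0.00226 without that library, but at the preset correlation, where most splits call the list, and the list mean was higher in mG in pairs 2 and 3 too, but 2 pairs are too few to settle it. A difference in cell cycling between mT and mG remains open and untested.

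With 10 splits of the 6 libraries a share under 0.05 cannot be reached, and 1 of the 10 gave as many genes, the real one with 123, where the highest other had 0 (the highest count at an unadjusted p under 0.05 was 1064, against 1978). For genes with at least a 2-fold change these were 119 and 0, likewise in 1 of 10 splits. With the replicate block, 4 splits part all 3 pairs, again too few, and 1 gave as many, the real one with 108 against 0 for the highest other (579 at an unadjusted p under 0.05 against 2259); the other 6 splits part 1 pair and join the libraries of the rest. For gene lists the real split gave 3 and the highest other 9, all 10 gave at least 3, and the 9 others at least 4. A count of lists above the real one in every other split may reflect a structure of the samples that camera at the preset correlation reads as list changes. Each other split still keeps part of any difference between mT and mG, and calls were counted in either direction. The Hox and proliferation lists were each called in 7 of the 10 splits and had adjusted p = 0.884 with an estimated correlation. With the list's own correlation as a fixed value, camera's unadjusted p was 0.0618 for the Hox list and 0.195 for the proliferation list. The calls of both lists at the preset correlation therefore carry little weight. The Wnt list was called in the real split alone, but 10 splits are too few to reach a share under 0.05. Its estimated correlation was -0.00302, and with that as a fixed value camera's unadjusted p was 8.35e-05. A correlation below the preset 0.01 can only lower p, so this value adds no support. Camera with an estimated correlation has 4 degrees of freedom, where the list's unadjusted p was 0.017 and its adjusted p 0.545. In fry's directional form its adjusted p was 0.0522, or 0.21 with the block.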
